A study of Mus musculus with 4 samples.

How the data were processed

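Gene expression was measured in mouse bone marrow cells at 4 times of a culture that forms osteoclasts, with 1 Affymetrix mouse array of 45101 probe sets at each time. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, and 250.0 ng of it was used to make biotinylated cRNA. The values deposited by the authors are the intensity of each probe set on a linear scale, and the submitters' processing notes name GCOS version 1.4 and MAS5. The target of any scaling is not given in the sources used here. The mean signal without the top and bottom 2% of probe sets was 281, 283, 298 and 278 on days 1, 4, 5 and 7, close but not equal. The median signal was 38.3, 34.3, 32.3 and 26.2. Detection calls and probe-level data were not used here. The number of arrays limits the precision of every value.

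Arrays were grouped by the day in their labels, and the 5 comparisons were day 4 over day 1, day 5 over day 4, day 7 over day 5, day 7 over day 4 and day 7 over day 1. The 64 control probe sets were left out. Signals under a floor of 32.4, the median of all other values, were set to the floor, and differences were taken on the log2 scale. A gene above the floor on 1 of 2 arrays has a bound, given as at least N-fold, and medians of gene lists count such genes at their bound. Of the 45037 other probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none; those with several or none were not named. The Entrez gene numbers of 34741 of the 34945 were found in a RefSeq table of the GRCm38.p6 assembly, which updated 0 symbols. No genome sequence was used, so no positions are given. Each of the 18194 genes was represented by the probe set with the highest mean log2 signal, and 12438 genes were above the floor on at least 1 array.

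With 1 array per group there was no test. A gene was called higher or lower at a difference of at least 2-fold, which is a threshold of size. The spread of 18 spiked control probe sets and the spread between probe sets of the same gene were used to describe technical precision; neither measures variation between cultures. The other probe sets of called genes were compared where they were above the floor on both arrays. Of these, 93.6% had the same direction on day 4 over day 1 and 94.5% on day 5 over day 4. The shares were 96.1% on day 7 over day 5, 95.7% on day 7 over day 4 and 92.4% on day 7 over day 1. Fewer reached 2-fold in that direction: 61.7%, 50.4%, 63.7%, 59.3% and 60.7% in the same order. The 37 gene lists, 12 of them of cell types, were fixed before the data were examined. The median of each list was given a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these arrays only. Of the osteoclast genes, the list of cell fusion holds 3, the list of V-ATPase subunits 2, the list of RANK and M-CSF signalling 3, the osteopetrosis list 11, the podosome list 3, the metalloproteinase list 1 and the platelet list 1.

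The rule for named genes was also fixed before the data were examined. It took the 10 genes with the largest positive and the 10 with the largest negative difference among genes above the floor on both arrays. It added, of genes above the floor on 1 array, the 5 in each direction with the highest signal there. It took up to 4 members of each list described with the largest differences, and always Acp5, Ctsk, Calcr, Mmp9, Nfatc1, Tnfrsf11a, Dcstamp, Ocstamp, Itgb3, Oscar, Cyp24a1, Vdr, Csf1r and Tnfsf11. Unnamed transcripts and antigen receptor segments could be left out.

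The alternatives were a floor at the 25th or 60th percentile of all values (8.43 and 68.9), no floor with 16 added to each signal, quantile normalization, scaling to the same median, the mean over probe sets of a gene, and leaving out probe sets designed to match several transcripts. Median scaling matched the medians of the probe sets that were above the floor on every array. A floor at the 75th percentile (254) was added after seeing the data. The counting and the list percentiles were tested on simulated data with 12298 genes. The day 4 array was the base, and a simulated day 5 was made from it by adding noise with an SD of 0.3 at every signal level. Changed genes were drawn from those above the floor on the day 4 array. Of 100.0 genes changed 4-fold 99 were called, and of as many changed 2.5-fold 82 were called, with 0 in the wrong direction. Of 12098 unchanged genes 8 were called, and 11 of 200.0 unchanged lists lay outside percentiles 2.5 and 97.5. These rates hold for that noise only, with no variation between cultures and no changed gene that starts at the floor. The pooled SD between probe sets was larger on day 4 over day 1 (0.41), day 7 over day 4 (0.36) and day 7 over day 1 (0.53). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.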

Results

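Gene expression was followed in mouse bone marrow cells on their way to osteoclasts, the multinucleated cells that resorb bone. Marrow was taken from female C57Bl/6J mice aged 12 weeks and grown for 3 days in medium with 10% serum and 10 nM vitamin D3. M-CSF (20 ng/ml), a growth factor of the macrophage lineage, and RANKL (40 ng/ml), the cytokine that drives osteoclast formation, were then added. Vitamin D3 stayed at 10 nM on days 5 and 7. RNA was hybridised to 1 array at each of 4 times: day 1 (the day of extraction), day 4 (after the 3 days with vitamin D3), day 5 and day 7 (both with M-CSF and RANKL). The labels of days 5 and 7 give 4 and 6 days of differentiation, which is read here as the whole time in culture. Each group thus held 1 array, and the labels do not say whether the samples came from 1 culture. No array of days 5 or 7 lacked M-CSF and RANKL, so their effect cannot be told apart from that of time in culture. With no replicates there is no test and no p-value, and every value below describes these 4 arrays. Of the 45101 probe sets, 52.6% of those that are not controls lay above the floor of 32.4 signal units on day 1, 50.9% on day 4, 49.9% on day 5 and 46.6% on day 7. For 12438 named genes the signal was above the floor on at least 1 array. Across these genes, which are not independent replicates, Pearson's r was 0.905 between days 1 and 4, 0.971 between days 4 and 5, 0.976 between days 5 and 7, and 0.844 between days 1 and 7.

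**Figure D1:**
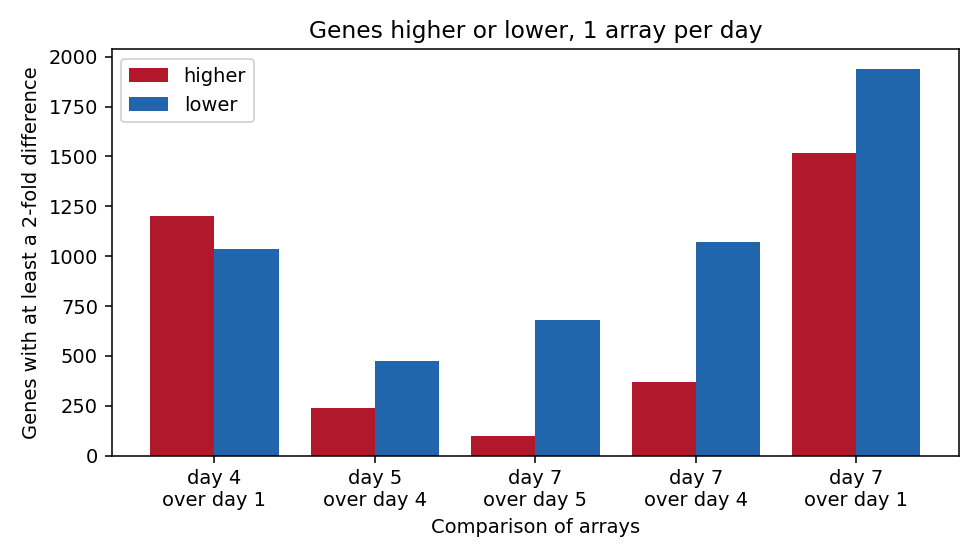
Number of genes (vertical axis) at least 2-fold higher or lower in each of the 5 comparisons of arrays (horizontal axis), with 1 array per day. The comparison of days 7 and 1 had 1516 higher and 1939 lower genes, and that of days 7 and 5 had 99 higher and 678 lower.

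The comparison of day 4 with day 1 asks what differs between fresh marrow and marrow kept for 3 days with vitamin D3 before any M-CSF or RANKL was added. Genes of bone marrow stroma and of osteoclasts were higher on day 4, and genes of red cells, neutrophils, B cells and the interferon response were lower. Of 30 measured stromal and osteoblast genes, 24 were at least 2-fold higher and 1 was lower, with a median log2 difference of 2.96. The gene for the matrix proteoglycan Ogn was at least 82.9-fold higher, the mineralisation inhibitor Mgp 26.9-fold, the chemokine gene Cxcl12 22.7-fold and the smooth muscle gene Tagln at least 16.6-fold. Of 22 measured osteoclast genes, 11 were at least 2-fold higher and 1 was lower, with a median of 0.90.

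Among the osteoclast genes, the gene for the collagen-degrading protease Ctsk was 14.0-fold higher on day 4, with a signal of 7934 against 568. The fusion genes Dcstamp and Ocstamp were at least 22.5-fold and at least 12.9-fold higher, and the receptor gene Oscar at least 3.69-fold. The tartrate-resistant phosphatase gene Acp5 was 2.38-fold higher, the gene for the RANKL receptor, Tnfrsf11a, 2.19-fold and the transcription factor gene Nfatc1 2.03-fold. Other probe sets of Nfatc1 differed by between -0.32 and 1.98 on the log2 scale, so its direction depends on the probe set. The protease gene Mmp9 had a log2 difference of 0.79 and the integrin gene Itgb3 of 0.12, and the calcitonin receptor gene Calcr was at the floor on both days. The carbonic anhydrase gene Car2 was 11.1-fold lower; it is also expressed in red cells. Of 19 subunits of the proton pump V-ATPase, 2 were higher and none was lower, and the largest difference was that of Atp6v0d2, 9.26-fold. Of 16 genes of osteoclast fusion, 7 were higher and 1 was lower (median 0.53), and of 17 metalloproteinases and their inhibitors 7 were higher, led by Mmp12 at 18.8-fold and Mmp2 at 10.6-fold. Of 16 listed genes for factors that osteoclasts can release to act on bone-forming cells, 8 were higher and 1 was lower, among them Vegfc at 7.41-fold, Igf1 at 5.94-fold and Pdgfa at 5.65-fold. These genes, and Mmp2, were higher on the same array as 24 of 30 stromal genes, and the array does not tell which cells expressed them.

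The gene for RANKL itself, Tnfsf11, was 7.17-fold higher on day 4, at a signal of 593 against 82.8, and that of M-CSF, Csf1, was 3.26-fold higher. Tnfsf11 is also on the stromal list, of which 24 of 30 genes were higher. A pair of genes that answer to vitamin D were higher as well: Cyp24a1, which encodes the enzyme that degrades the hormone, by 5.88-fold and the receptor gene Vdr by 4.55-fold. In all, 4 of 12 vitamin D response genes were higher and 2 were lower. The M-CSF receptor gene Csf1r had a log2 difference of -0.11. Of 23 macrophage genes, 6 were higher and 3 were lower (median 0.39). Marco was 6.87-fold higher, the mannose receptor gene Mrc1 5.15-fold and the complement gene C1qa 3.37-fold, while Ccr2, the chemokine receptor gene of inflammatory monocytes, was 32.1-fold lower.

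Other genes with the largest differences among those above the floor on both arrays were, on the higher side, Ptx3 (54.6-fold), the collagen-processing gene Pcolce (35.0-fold), Cpe (28.9-fold), Gpx8 (19.0-fold), the mesenchymal transcription factor gene Prrx1 (18-fold), the leukotriene synthase gene Ltc4s (17.8-fold) and Cyp1b1 (17.0-fold). Islr, Rspo2, Mme and Aldh1a2 were at the floor on day 1 and at least 47.3-fold, 33.1-fold, 32.4-fold and 32.3-fold higher. On the lower side, 13 of 17 erythroid genes were lower and none was higher (median -4.22). Of these 17 genes 5 were above the floor on day 4, so the median is a bound. The gene for the first enzyme of haem synthesis in red cells, Alas2, was at least 256-fold lower and the anion exchanger gene Slc4a1 at least 201-fold. Trim10, Hbb-b2 and Bpgm, of red cells too, were at least 66.3-fold, at least 60.5-fold and 43.2-fold lower, and Tmcc2 and Tent5c were 32.7-fold and 30.5-fold lower. Neutrophil genes were lower in 15 of 21 cases (median -2.34), such as Fcnb at 17.7-fold, Ms4a3 at 12.8-fold and Elane at 10.6-fold. B cell genes were lower in 16 of 23 cases (median -1.49), with Vpreb1 at 15.1-fold and Igll1 at 8.35-fold. Of 13 genes of mast cells, basophils and eosinophils, 9 were lower, with Epx at least 79.2-fold, Prg3 22.9-fold and Prg2 10.3-fold. Of 9 genes of T and NK cells 5 were lower, with Nkg7 at 18.4-fold, and Ear3 and Ly6i were 24.6-fold and 20.7-fold lower. Megakaryocyte and platelet genes, in contrast, were at similar levels on both days, with 1 of 16 lower, none higher and a median of 0.17.

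Of 22 interferon response genes, 17 were lower on day 4 and 1 was higher (median -2.01). The antiviral genes Rsad2, Usp18, Oasl2 and Ifit1 were 34.3-fold, 13.3-fold, 7.45-fold and 7.20-fold lower, and Isg20 31.8-fold. Of 22 immediate early and stress genes 9 were lower and 1 was higher, with Nr4a1 at 5.08-fold lower and Fosl1 at 5.10-fold higher. Among genes of mitosis 6 of 24 were lower (median -0.63), led by Nusap1 at 2.78-fold and Mki67 at 2.62-fold, and 7 of 14 progenitor genes were lower, with Erg at 7.39-fold and Myb at 7.15-fold. Dendritic cell genes were mixed, with 7 of 16 lower and 3 higher.

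Over all genes, 1202 were at least 2-fold higher and 1036 at least 2-fold lower on day 4, and the median log2 difference of the 10612 genes above the floor on both arrays was 0.05. The list medians lay at percentile 100 of 10000 random lists of matched level for the stromal and osteoclast genes and at percentile 0 for the erythroid, neutrophil, B cell and interferon genes. As measures of precision, 18 spiked control probe sets had an SD of 0.17 on the log2 scale between these arrays, and probe sets of the same gene a pooled SD of 0.41.

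**Figure D2:**
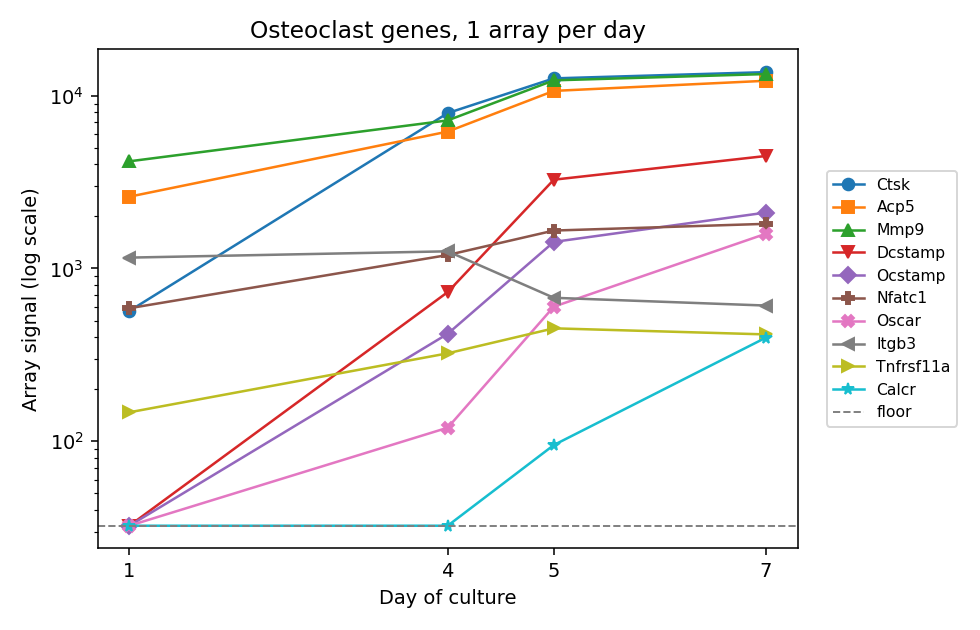
Array signal on a log axis (vertical) of 10 osteoclast genes on days 1, 4, 5 and 7 (horizontal), 1 array per day, with values under the floor drawn at the floor (dashed line). Ctsk was at 568 on day 1 and 7934 on day 4, whereas Calcr was above the floor from day 5 on, at 95.1 and then 398.

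Day 5 against day 4 covers the first interval with M-CSF and RANKL. Osteoclast genes were higher again, with 6 of 22 at least 2-fold higher, none lower and a median of 0.61. Oscar was 5.02-fold higher, Dcstamp 4.47-fold, Ocstamp 3.40-fold and Car2 3.21-fold, and Calcr, at the floor on day 4, was at least 2.93-fold higher. The log2 differences of Acp5, Mmp9 and Ctsk, whose signals were already 6200, 7198 and 7934 on day 4, were 0.78, 0.77 and 0.67. Those of Nfatc1 and Tnfrsf11a were 0.47 and 0.48. That of Itgb3, which is also on the platelet list, was -0.89, where a second probe set gave 0.14.

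Genes of DNA synthesis were higher on day 5 as well. Of 25 S phase genes, 16 were at least 2-fold higher and none was lower (median 1.05), among them the replication gene Gins1 at 2.97-fold, the cyclin gene Ccne2 at 2.84-fold, the origin licensing gene Cdc6 at 2.70-fold and Uhrf1 at 2.51-fold. Of 24 genes of G2 and mitosis none reached 2-fold, with a median of 0.72. Of 23 cytokine and chemokine genes 6 were higher, 2 were lower and 15 were neither. The chemokine genes Ccl12, Ccl7 and Ccl2 were 19.8-fold, 9.35-fold and 5.67-fold higher, and Ccl5 was 4.37-fold lower. Other genes among the 10 with the largest positive differences, of those above the floor on both arrays, were the esterase gene Ces5a (11-fold), the ephrin gene Efnb2 (5.76-fold), Edil3 (5.59-fold), Mboat1 (4.82-fold), the urokinase gene Plau (4.64-fold) and the ketone body enzyme gene Bdh1 (4.60-fold). Ifi202b, Sema3f, Cd248 and Nppc were at the floor on day 4 and at least 4.73-fold, 3.54-fold, 3.02-fold and 2.99-fold higher.

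Genes of antigen presentation, platelets, neutrophils and B cells were lower on day 5. Of 11 genes of MHC class II presentation, 8 were at least 2-fold lower (median -2.02), with H2-Eb1 at 5.95-fold, H2-Aa at 5.53-fold and H2-Ab1 at 4.98-fold. Of 16 megakaryocyte and platelet genes 13 were lower (median -1.88), such as Rab27b at 4.87-fold, Gp5 at 4.81-fold and Vwf at 4.64-fold. Neutrophil genes were lower in 15 of 21 cases (median -1.50), with Mpo at 4.84-fold and Csf3r at 4.17-fold, and B cell genes in 11 of 23 cases (median -0.90), with Ms4a1 at 6.73-fold, Spib at 6.71-fold and Pou2af1 at 6.49-fold. Dendritic cell genes were lower in 7 of 16 cases, with Clec10a at 6.05-fold and Cd83 at 4.72-fold. The growth factor gene Bmp2 was 8.25-fold lower, the chemokine receptor gene Cxcr4 7.57-fold, the progenitor gene Myb 7.55-fold, Bex1 5.74-fold and Gucy1a1 5.68-fold. Slc14a1, Dnah2, Retnla, H2-Ob and Gpr162 were at the floor on day 5 and at least 8.53-fold, 6.42-fold, 4.59-fold, 4.30-fold and 4.27-fold lower. Macrophage genes had 2 of 23 higher, Msr1 at 2.39-fold and Itgam at 2.25-fold, and 3 lower, among them Mertk at 2.35-fold. Irf8, a transcription factor gene that restrains osteoclast formation, was 2.07-fold lower, the only one of 17 inhibitor genes past 2-fold.

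Stromal genes were not at lower levels on day 5, with none of 30 higher, 1 lower (Vcam1, 2.44-fold) and a median of 0.37. The log2 difference of Tnfsf11 was 0.50, that of Cyp24a1 0.05, that of Vdr -0.52 and that of Csf1r 0.09. Over all genes, 239 were at least 2-fold higher and 477 at least 2-fold lower, with a median of 0.06 for genes above the floor on both arrays. The spiked controls had an SD of 0.10 and probe sets of a gene a pooled SD of 0.29. The percentile among random lists was 100 for the osteoclast, S phase and stromal lists and 0 for the MHC class II, platelet, neutrophil and B cell lists.

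Day 7 against day 5 covers the later interval with both cytokines. Few osteoclast genes differed by 2-fold at this step: Calcr was 4.19-fold higher and Oscar 2.64-fold, with no gene of the 22 lower and a median of 0.17. The log2 differences of the other named osteoclast genes were 0.56 for Ocstamp, 0.46 for Dcstamp, 0.19 for Acp5, 0.13 for Nfatc1, 0.12 for Ctsk and Mmp9, -0.12 for Tnfrsf11a and -0.15 for Itgb3. Genes of cholesterol synthesis had 3 of 19 higher (6 after median scaling), none lower and a median of 0.76, with the farnesyl diphosphate synthase gene Fdps at 2.31-fold, the feedback regulator gene Insig1 at 2.16-fold and Lss at 2.05-fold. Among genes above the floor on both arrays, the 10 largest positive differences also included the complement regulator gene Cd55 (6.52-fold), the carbonyl reductase gene Cbr2 (6.10-fold), the lectin genes Mgl2 (5.34-fold) and Clec10a (4.89-fold), Pcp4l1 (4.33-fold), the chemokine gene Ccl8 (4.11-fold), Rnase6 (4.02-fold), Ifi27l2a (3.96-fold) and Grap (3.79-fold). Tox2, Sgsm3, Ppm1j, Rasgrp3 and Ntn1 were at the floor on day 5 and at least 5.22-fold, 3.32-fold, 3.30-fold, 2.80-fold and 2.57-fold higher.

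Stromal genes were lower on day 7 than on day 5, 15 of 30 with none higher (median -0.99). They included Tnfsf11 at 4.05-fold, the collagen cross-linking gene Loxl1 at 3.54-fold, the collagen gene Col1a1 at 3.48-fold and the leptin receptor gene Lepr at 3.34-fold. Csf1 was 2.73-fold lower and Vdr 2.53-fold lower, and the log2 difference of Cyp24a1 was -0.99 and that of Csf1r -0.01. Neutrophil genes were lower in 16 of 21 cases (median -2.35), such as Ltf at 9.76-fold, Lcn2 at 9.72-fold, Camp at 7.98-fold and S100a9 at 7.96-fold, and platelet genes in 10 of 16 cases (median -1.40), with Ppbp at 24.4-fold and Tubb1 at 7.64-fold. Of the cytokine genes 9 of 23 were lower and 2 were higher (5 after median scaling); Cxcl3 was at least 32-fold lower, the arginase gene Arg1 13.2-fold and the prostaglandin synthase gene Ptgs2 11.6-fold. Prg2 and Mcpt8, of eosinophils and basophils, were 9.32-fold and 7.94-fold lower, and Serpinb1a, Cd177, Ctsg and Gp1bb were at least 7.17-fold, 6.87-fold, 6.15-fold and 5.89-fold lower. Of 17 inhibitors of osteoclast formation 3 were lower, Id1 at 3.57-fold, Id3 at 2.38-fold and Socs3 at 2.29-fold, and of the 17 metalloproteinases and inhibitors 5 were lower, with Mmp8 at 4.24-fold and Adam19 at 3.79-fold.

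Over all genes, 99 were at least 2-fold higher and 678 at least 2-fold lower on day 7 than on day 5, so that 12.7% of these genes were higher. This split depended on how the arrays were scaled: quantile normalization gave 195 higher and 424 lower (31.5% higher) and scaling to the same median gave 183 and 491 (27.2%). The median log2 difference of all genes was -0.09 as deposited, 0.01 after quantile normalization and 0.03 after median scaling. Relative to it, the median of the stromal and osteoblast list was -0.90 as deposited and -0.87 after median scaling, and that of the osteoclast list 0.26 and 0.32. Percentiles among random lists were 100 for cholesterol synthesis and 0 for stromal, neutrophil and platelet genes. The pooled SD between probe sets of a gene was 0.26.

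Day 7 against day 4 covers the whole time with M-CSF and RANKL, and differences over it also hold the effect of time in culture. Osteoclast genes were higher in 7 of 22 cases and lower in 1, Itgb3 at 2.06-fold, with a median of 0.66. Under both other scalings 0 were lower by 2-fold. Itgb3 is also on the platelet list, of which 14 of 16 genes were lower here, and the array does not tell which cells expressed it. Oscar was 13.3-fold higher, Calcr at least 12.3-fold, Dcstamp 6.14-fold, Ocstamp 5.03-fold and Car2 3.13-fold. The differences of Acp5 (0.98), Mmp9 (0.89), Ctsk (0.79), Nfatc1 (0.60) and Tnfrsf11a (0.36) stayed under 1 on the log2 scale. Related lists did not follow as a whole. Of 16 genes of osteoclast fusion, 2 were higher and 1 was lower (median 0.002). Of 19 osteopetrosis genes, 2 were higher and 6 were lower (median -0.20, percentile 4.05). Of 28 podosome genes, 0 were higher and 2 were lower (median 0.12). Of 19 V-ATPase subunits, 0 were higher or lower by 2-fold (median 0.34). The monocyte chemokine genes Ccl12, Ccl8, Ccl7 and Ccl2 were 35.3-fold, 16.9-fold, 11.7-fold and 7.52-fold higher, and Plau, Bdh1, the metallothionein gene Mt3, Tmem204 and the folate receptor gene Folr2 were 11.9-fold, 9.57-fold, 9.17-fold, 7.67-fold and 7.61-fold higher. Prr15, Cyb561 and P2rx5 were at least 5.57-fold, 4.80-fold and 3.82-fold higher, and 1 further gene of this kind is an unnamed transcript and is left out.

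Genes of cell division were higher on day 7 than on day 4, 13 of 24 for G2 and mitosis (median 1.02) and 8 of 25 for S phase (median 0.84; 13 genes after median scaling), with none lower in either list. Birc5 was 2.75-fold higher, the mitotic kinase gene Aurka and the cyclin gene Ccnb2 2.49-fold, Gins1 2.94-fold and the thymidine kinase gene Tk1 2.64-fold. On the lower side, all 21 neutrophil genes were at least 2-fold lower (median -3.77), with Ltf at 29.2-fold, Mpo at 24.7-fold, Lcn2 at 23.6-fold and Camp at 22.6-fold. So were 14 of 16 platelet genes (median -3.19), with Ppbp at 80.2-fold and Tubb1 at 33.3-fold, and 8 of 11 MHC class II genes (median -2.11), with H2-Aa at 27.1-fold and H2-Eb1 at 26.9-fold. B cell genes were lower in 12 of 23 cases (median -1.40), with Ms4a1 at least 21.7-fold. Prg2 was 31.0-fold and Cxcr4 22.3-fold lower, and Gp1bb, Cd177, Serpinb1a and Gp5 were at least 24.4-fold, 22.6-fold, 21.8-fold and 20.0-fold lower. Stromal genes were lower in 7 of 30 cases with a median of -0.58. Vdr was 3.62-fold and Tnfsf11 2.87-fold lower, and the log2 differences of Cyp24a1 and Csf1r were -0.94 and 0.07. Interferon genes had 3 of 22 higher (5 after median scaling) and none lower (median 0.32), among them Usp18 at 2.51-fold.

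Over all genes, 367 were at least 2-fold higher and 1071 at least 2-fold lower on day 7 than on day 4, 25.5% higher; quantile normalization gave 570 and 732 (43.8% higher) and median scaling 548 and 824 (39.9%). The percentile was 100 for the osteoclast, S phase and mitosis lists and 0 for the neutrophil, platelet, B cell and MHC class II lists. The pooled SD between probe sets of a gene was 0.36.

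Day 7 against day 1 covers the whole culture. Of the 22 osteoclast genes, 16 were at least 2-fold higher and 1, Car2, was 3.55-fold lower, with a median of 1.71 and a percentile of 100. Dcstamp was at least 138-fold higher, Ocstamp at least 65.0-fold, Oscar at least 49.0-fold, Ctsk 24.1-fold and Calcr at least 12.3-fold. Acp5 was 4.69-fold higher, Mmp9 3.20-fold, Nfatc1 3.08-fold and Tnfrsf11a 2.82-fold, and Itgb3, also on the platelet list, had a log2 difference of -0.92. Other probe sets of Nfatc1 ranged from -0.33 to 2.94. For the 15 of these 16 genes that were above the floor on day 1 or day 4, a median of 63.0% of the log2 difference between days 1 and 7 was already there on day 4 (range 26.3% to 85.9%, the latter for Atp6v0d2) and 92.0% on day 5. Shares of genes at the floor on day 1 are bounds, and Calcr, at the floor on days 1 and 4, has no measured share; with it counted at 0 the medians were 62.2% and 91.6%. Lists that share genes with the osteoclast list differed. Of 16 genes of osteoclast fusion, 9 were higher and 1 lower (median 1.04, percentile 100), and of 17 metalloproteinases and inhibitors 9 were higher and 2 lower (median 1.22, percentile 100). Of 19 osteopetrosis genes, 11 of them also osteoclast genes, 6 were higher and 3 lower (median 0.22, percentile 60.02). Of 28 podosome genes, 3 of them also osteoclast genes, 6 were higher and 3 lower, with Myo10 5.23-fold higher and Zyx 5.71-fold lower; the median of -0.09 (percentile 4.30) lay between -0.07 and 0.04 under the other scalings. Among genes above the floor on both arrays, the largest positive differences outside the osteoclast list were those of the sodium-proton exchanger gene Slc9b2 (82.3-fold), Ccl12 (81.9-fold), Cpe (49.1-fold), Plau (44.7-fold), Mgp (36.4-fold), the actin-severing gene Scin (36.2-fold), Ccl7 (35.2-fold), Bdh1 (32.6-fold) and Cxcl12 (31.8-fold), and Mt3 and Ogn were at least 62.9-fold and 54.2-fold higher.

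Genes of mitochondrial energy production were higher on day 7 than on day 1, mostly by less than 2-fold in the respiratory chain. There 11 of 37 reached 2-fold and 26 did not (median 0.85). In the citrate cycle 9 of 18 reached it (median 1.01), with none lower in either list. Of all genes, 12.2% were at least 2-fold higher. After quantile normalization 6 genes were higher in each list, against 1998 of all 12478 genes, and after median scaling 18 and 16. Uqcrfs1 was 2.66-fold higher, Sdhd 2.51-fold, Idh3a 3.18-fold and Fh1 3.16-fold, and of 11 genes of mitochondrial biogenesis 2 were at least 2-fold higher and 9 were neither, with the regulator gene Ppargc1b 3.60-fold higher. Glycolysis genes were mixed, 3 of 18 higher and 2 lower, with Aldoc 8.12-fold higher and the hexokinase gene Hk2 2.68-fold lower. V-ATPase subunits were higher in 5 of 19 cases (median 0.63; 2 cases after quantile normalization), with Atp6v0d2 at 13.3-fold and Atp6v1h at 3.23-fold, and cholesterol synthesis genes in 8 of 19 cases (median 0.70), with Lss at 4.02-fold. Lysosome genes had 1 of 26 higher, Glb1 at 3.64-fold, and 1 lower (3 and 0 after median scaling). Stromal genes were still higher than on day 1 in 21 of 30 cases and lower in 2 (median 1.96). Genes of RANK and M-CSF signalling had 3 of 30 higher and 6 lower (3 lower after median scaling), with the kinase gene Syk 3.00-fold and Plcg2 2.95-fold lower. Cyp24a1 was 3.08-fold higher, Tnfsf11 had a log2 difference of 1.32, Vdr of 0.33 and Csf1r of -0.04.

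All 21 neutrophil genes were lower on day 7 than on day 1 (median -5.59), with Cd177 at least 173-fold, Ctsg at least 166-fold, Mpo 162-fold, Prtn3 73.1-fold and Ltf 65.3-fold. Prg2 was 318-fold lower, Tent5c 112-fold, Mcemp1 109-fold, Wfdc21 81.9-fold, Plbd1 69.8-fold, Lrg1 68.4-fold and Ms4a3 65.9-fold, and Serpinb1a was at least 132-fold lower. Erythroid genes were lower in 14 of 17 cases, with Alas2 and Slc4a1 at least 256-fold and 201-fold, platelet genes in 13 of 16 cases, B cell genes in 18 of 23 cases and MHC class II genes in 9 of 11 cases. Interferon genes were lower in 15 of 22 cases and higher in 1 (median -1.49). Progenitor genes were lower in 9 of 14 cases, with Myb at least 124-fold, endothelial genes in 5 of 16 cases, with Pecam1 at 6.61-fold, and dendritic cell genes in 8 of 16 cases with 1 higher (3 after median scaling). Macrophage genes went both ways, 7 of 23 higher and 4 lower, with a median of 0.08 that was -0.12 after quantile normalization and 0.22 after median scaling.

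Over all genes, 1516 were at least 2-fold higher and 1939 at least 2-fold lower on day 7 than on day 1, 43.9% higher; the split turned to 1998 and 1560 (56.2%) after quantile normalization and to 1891 and 1673 (53.1%) after median scaling, which moved the median of all genes from 0 to 0.14 and 0.11. Relative to that shifted median, the osteoclast list lay at 1.56 after quantile normalization and at 1.74 after median scaling. The pooled SD between probe sets of a gene was 0.53.

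**Figure D3:**
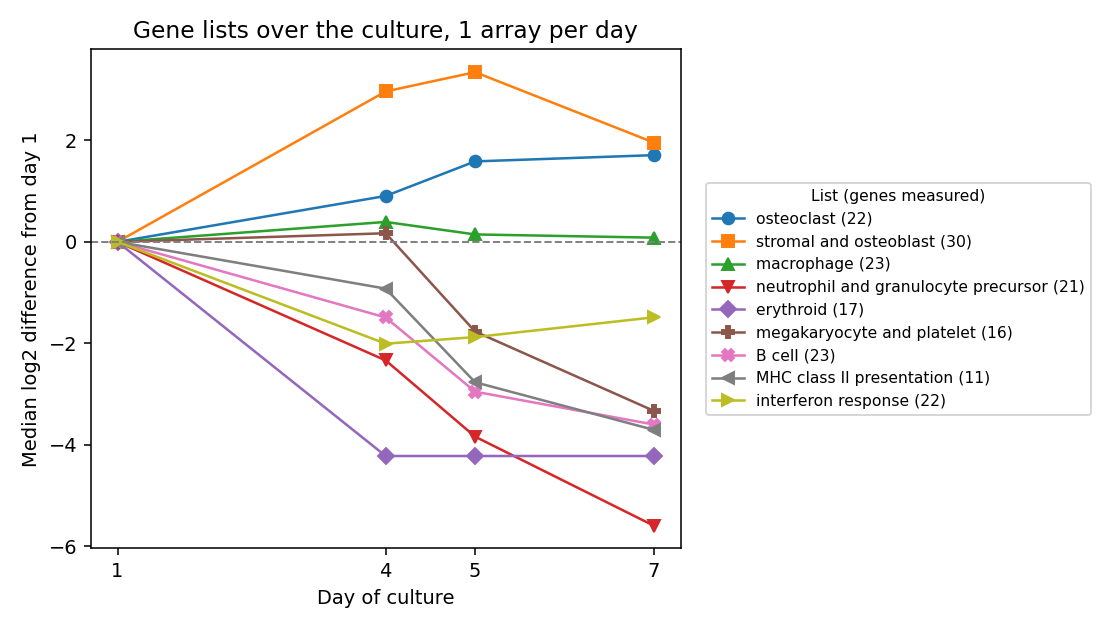
Median log2 difference from day 1 (vertical axis) of 9 gene lists on days 1, 4, 5 and 7 (horizontal axis), 1 array per day; the number of genes measured is in the legend. The osteoclast list reached 1.71 and the stromal list 1.96 on day 7, and the neutrophil list -5.59. Genes at the floor enter at their bound, and 5, 4 and 3 of 17 erythroid genes were above it on days 4, 5 and 7.

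Over the course of the culture, 1426 genes had a range of at least 4-fold. Of these 715 had their highest value on day 1, 99 on day 4, 438 on day 5 and 174 on day 7. These counts depended on the processing: quantile normalization gave 262 genes with a 4-fold range highest on day 7, and the mean over probe sets gave 61 genes with a 4-fold range highest on day 4 and 278 genes with a 4-fold range highest on day 5. A floor at the 25th percentile gave 200, 687 and 289 on days 4, 5 and 7. Of the genes at least 2-fold higher on day 4 than on day 1, 314 were at least 2-fold lower on day 7 than on day 5, against 65.5 for independent lists, and 21 were higher, against 9.57. Of those lower on day 4, 123 were lower again on day 7 than on day 5 (56.5 for independent lists), and 14 were higher (8.25). All 4 overlaps lay above the value for independent lists, which takes each of the 12438 genes as equally likely to be called. These comparisons share no array. Stromal genes were at their highest median on day 5, osteoclast genes on day 7. Ribosomal protein genes, taken as a control list of 16, had medians between -0.06 and 0.14 in the 5 comparisons, where the lowest, that of day 7 over day 5, lay between -0.04 and 0.12 under the other scalings. The ribosomal gene Rpl37 was 4.48-fold higher on day 4 than on day 1. The ratio of the 3' to the 5' probe sets of Actb was 1.21, 1.20, 1.18 and 1.13 on days 1, 4, 5 and 7, and the median signal of the 18S probe sets 3227, 4140, 6362 and 6117.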

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

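The floor at the 75th percentile was chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group held 1 array and no test was made. Some list medians near 0 changed sign under another scaling, such as that of RANK and M-CSF signalling on day 7 over day 5, from -0.11 to between 0.03 and 0.07, and that of the macrophage list on day 7 over day 1, from 0.08 to -0.12 after quantile normalization. The balance of higher and lower genes on day 7 over day 1 turned from 1516 and 1939 to 1998 and 1560.0 after quantile normalization and to 1891 and 1673 after median scaling. With the floor at the 25th percentile, day 4 over day 1 had 1878 higher and 1717 lower genes, day 5 over day 4 had 746 and 970.0, day 7 over day 5 had 465 and 1354, and day 7 over day 4 had 852 and 1748; 200 genes with a 4-fold range highest on day 4 were counted, 687 genes with a 4-fold range highest on day 5 and 289 genes with a 4-fold range highest on day 7. With the floor at the 60th percentile, 61 were highest on day 4. With no floor and 16 added to each signal, 150 genes were higher on day 7 than on day 5. Quantile normalization gave 195 higher and 424 lower genes for day 7 over day 5, 570.0 higher for day 7 over day 4 and 262 genes highest on day 7, and scaling to the same median 183 higher for day 7 over day 5. The mean over probe sets gave 150 higher for day 5 over day 4, 421 lower for day 7 over day 5, and 61 and 278 genes highest on days 4 and 5. With the floor at the 75th percentile, counts of higher and lower genes were 408 and 491 for day 4 over day 1, 106 and 149 for day 5 over day 4, 37 and 180.0 for day 7 over day 5, 179 and 342 for day 7 over day 4, and 737 and 951 for day 7 over day 1; 267, 18, 95 and 63 genes were highest on days 1, 4, 5 and 7. A higher floor leaves fewer genes that can pass, and a lower one more; the cause of the other shifts was not tested. Leaving out probe sets that match several transcripts kept these counts within 1.5 times. In what follows, the value of a named gene moved if it changed by more than the pooled SD between probe sets in that comparison. These values cover the genes named for the largest differences, above the floor on both arrays or on 1 array, and Cyp24a1, Vdr, Csf1r and Tnfsf11. Genes named only as members of a list, the osteoclast list included, were not counted among them. A count moved if it changed by more than 1.5 times, or to or from 0. Of the values of named genes, 110.0 moved and 41 did not with the floor at the 75th percentile, 76 and 94 with that at the 60th, 33 and 137 with that at the 25th, 34 and 136 with no floor, 38 and 132 under the mean over probe sets, 10 and 160.0 under quantile normalization, 0 and 170.0 under median scaling, and 1 and 162 without probe sets that match several transcripts. Of the counts in gene lists, in the same order of settings, 98, 25, 41, 16, 46, 34, 34 and 15 moved and 270.0, 343, 327, 352, 322, 334, 334 and 353 did not. Median scaling shifts all genes above the floor alike, by less than the pooled SDs, so its 0 moved values say nothing about single genes. Between 46.6% and 52.6% of probe sets were above the floor on each array, and folds of genes at the floor are bounds.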

Other observations

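All tests and gene families in this part were chosen after the values were seen. The 3 measured metallothionein genes, whose products bind zinc and copper, were at least 2-fold higher on day 7 than on day 1, Mt1 by 2.88-fold, Mt2 by 11.2-fold and Mt3 by at least 62.9-fold. Of 7 aldo-keto reductase genes with Akr1 symbols, 6 were higher, with Akr1b8 at 16.4-fold (signal 7079.9 against 432) and Akr1c18 at least 18.2-fold. Of 15 glutathione S-transferase genes with Gsta, Gstm, Gsto, Gstp or Gstt symbols, 7 were at least 2-fold higher and 0 at least 2-fold lower. Under quantile normalization 9 were higher, and under median scaling 8. Gsta2 was at least 39.6-fold and Gstm2 11.4-fold higher. The log2 differences of Gstm1, Gstm3 and Gstp1 were -0.47, -0.18 and -0.39. Of the D-type cyclins, Ccnd1 was 23.04-fold higher (4514 against 196) and Ccnd3 6.00-fold lower (358 against 2150.4), while the log2 difference of Ccnd2 was 0.81. Of 6 schlafen genes 5 were lower, led by Slfn4 at 58.8-fold, and Slfn9 had a log2 difference of 0.83, at least 2-fold higher under quantile normalization.

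A small set of genes was lower on day 5 than on both neighbouring days. Of 10522 genes, 11 were at least 2-fold lower than on days 4 and 7, and 20 were higher; the counts were 19 and 11 under quantile normalization and 16 and 13 under median scaling. The lectin gene Clec10a had signals of 1640.3, 271 and 1326 on days 4, 5 and 7, Mgl2 of 154, 77 and 411, Cbr2 of 1424, 458 and 2795, and the clock-controlled gene Dbp of 533, 115 and 377. Both comparisons rest on the single day 5 array.

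Osteoclast genes were higher on day 4 than on day 1, before M-CSF and RANKL were added. A difference in scaling does not account for this, since 11 of 22 genes stayed at least 2-fold higher after quantile normalization. Loss of other marrow cells as the whole cause was taken to raise every macrophage transcript alike. By any amount, 10 of 23 macrophage genes were lower, as deposited and under both other scalings. As deposited, 3 were at least 2-fold lower and 6 at least 2-fold higher. Csf1r, at -0.11 on the log2 scale, lay within the pooled SD of 0.41 between probe sets, and C1qa was at 1.75. The count cannot decide whether such loss was the whole cause, a part or none of it. Neutrophils, whose listed genes were mostly lower on day 4, share some of these genes, such as Itgam and Lyz2. RANKL made in the culture may also contribute, as the log2 difference of Tnfsf11 was 2.84. Tnfsf11 is on the stromal list, whose median at this step was 2.96. With no array of cells cultured without vitamin D3, the possibilities cannot be told apart.

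Interferon-response genes were lower on day 4 than on day 1. Scaling does not account for it, with 17 of 22 genes still at least 2-fold lower after quantile normalization. Loss of neutrophils as the whole cause was taken to lower the interferon list further from day 4 to day 7. The neutrophil list then had a median of -3.77 and the interferon list one of 0.32. Transcripts left on day 4 may come from other cells, so this does not decide the first step, when the medians were -2.34 and -2.01. Loss of other cells was not tested. The end of a stimulus present in the animal may explain the lower interferon genes. Their list stayed at -1.49 on day 7 over day 1, but day 1 is the single uncultured array, so handling and culture remain open.

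Stromal genes were lower on day 7 than on day 5. With the arrays scaled to the same median, 12 genes of the list were still at least 2-fold lower, which argues against scaling as the cause. A loss of stromal cells that lowers every transcript alike could not be settled: the interquartile range was 0.97, with quartiles of -1.38 and -0.41 against a pooled SD between probe sets of 0.26. An effect of M-CSF and RANKL on stromal cells was not tested.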
